A study of Mus musculus with 6 samples.

How the data were processed

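RNA was measured in the dorsal striatum of mice aged 1 year, in 3 samples from mice heterozygous for Ash1l and 3 from wild type (WT) mice, all on a C57BL/6 background per the labels. Tissue was lysed in TRIzol, and libraries were made with a stranded mRNA kit, per the labels' protocols. The submitters' processing notes name CASAVA, FastQC, HISAT2, StringTie and edgeR and the build GRCm38; the role, order, version and settings of each tool are not given in the sources used here. The labels describe the samples as separate replicates of a genotype but do not say outright that each is a separate animal, so p-values measure the spread between these samples.

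The deposited table holds raw read counts per gene for the 6 libraries, and the authors also gave FPKM values for the same genes. The per-sample files hold the same counts as the series table for all 6 libraries. FPKM in the deposited table equals the count scaled by a fixed length per gene and by the library total: of genes with a mean count of at least 10, 99.0% gave a whole length within 0.1 base. The table lists 34745 genes, of which 21693 had a count in some library. Of these 34745 gene identifiers, 34344 were in the GENCODE annotation of the same build used here, and 27776 had the same start and end. Whether the authors' counting used strand is not given in the sources used here, so overlapping and antisense genes are treated as uncertain.

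Library totals ran from 12080663 to 18798694 counts. Intervals and floors quoted from counts cover counting error only, since no molecular identifiers are described.

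Genes were tested on the deposited counts with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3), with robust dispersion, TMM scaling, the default expression filter (minimum count 10) and genotype as the single term. The filter left 15267 genes, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Normalised counts are CPM on the TMM scale, given as mean ± SD, and fold changes are log2 of Ash1l het over WT with the standard error (SE) of the fit. Gene lists were fixed before the data were examined: 39 lists with 619 genes, of which 38 were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and adjusted over the lists. Camera was repeated with an estimated correlation, and fry was run beside it. Genes named in the text follow a rule fixed at the same time: Ash1l, then called genes whose groups do not overlap with a mean of at least 1 CPM (up to 12 per direction), then, with under 10 calls, the 10 smallest unadjusted p-values, then up to 4 members of each called list and up to 2 of each other list by smallest p. Genes named outside this rule are marked as chosen after their values were seen.

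The steps were tested on simulated counts for the Ash1l het against WT comparison, drawn from the real means, library sizes and dispersions, with 200 genes changed. Among 15061 simulated genes the quasi-likelihood test recovered 8% of 50 genes changed 1.5-fold, 52% of 50 changed 2-fold, 80% of 50 changed 3-fold and 88% of 50 changed 4-fold. Of its 129 calls, 15 (11.6%) were genes that had not been changed, which is above the nominal 5% set by the threshold. The counts were drawn a single time, and the recovery rates depend on the 200 changed genes. With fewer changed genes the Benjamini-Hochberg cutoff on the unadjusted p is stricter. The real comparison gave 2 calls, so these rates probably overstate recovery there. DESeq2 1.42.0 and the exact test of edgeR each made 154 calls in the same simulated data, 32 of them (20.8%) on unchanged genes. A simulated list of 20 genes raised 1.5-fold gave an adjusted p of 1.22e-17, and 0 of 40 unchanged lists were called; the simulation held no correlation between genes.

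Alternatives fixed before the data were examined were DESeq2, the exact test of edgeR, limma-voom, RLE and upper-quartile scaling, no filter and a stricter filter (1 CPM in 3 libraries), limma on log2(FPKM + 0.1) and log2(FPKM + 1) for genes with a mean FPKM of at least 0.5, the replicate number as a block, 1 surrogate variable (sva 3.50.0), thresholds of 0.10 and of 1.5-fold, and each library left out. Removal of the 13 mitochondrially encoded genes and a globin covariate were added after the data were seen.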

Results

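Transcript levels in the dorsal striatum were compared between 3 libraries from Ash1l heterozygous (Ash1l het) mice and 3 from WT mice, aged 1 year. Ash1l encodes a histone methyltransferase acting on lysine 36 of histone H3. The libraries held 14573790, 14421259 and 18798694 counts in Ash1l het and 12080663, 17381781 and 17368823 in WT. Mitochondrially encoded genes took 15.9% to 18.8% of the counts. The labels' protocol describes male mice, but Xist, which is transcribed from the inactive X chromosome of females, lay between 1956 and 2957 CPM in all 6 libraries. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y together had 0 counts in 5 libraries and 1 count in WT replicate 1.

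The targeted gene itself was examined first. Ash1l (ENSMUSG00000028053; GRCm38 chromosome 3, 88950622 to 89079375, plus strand) stood at 244 ± 42.6 CPM in Ash1l het and 299 ± 8.15 CPM in WT (SD, n = 3 each). Each of the 3 Ash1l het libraries, at 281, 198 and 253 CPM, lay below each WT library, at 308, 295 and 293 CPM. The log2 fold change was -0.29 (SE 0.13). The edgeR quasi-likelihood p was 0.0577 unadjusted and 0.858 adjusted over all tested genes, so the difference did not pass. A two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. The fitted level was 81.7% of WT (95% interval 66.2% to 100.8%), which excludes the 50% that loss of 1 copy without compensation would leave in whole-gene counts. Without Ash1l het replicate 2 the log2 fold change was -0.16. The position of the mutation in the gene is not given in the sources used here, so whether whole-gene counts hold transcripts of the altered allele is open.

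Across 15267 genes, 2 passed the edgeR quasi-likelihood test, and both were higher in Ash1l het. Usp46, a deubiquitinating enzyme (ENSMUSG00000054814; chromosome 5, 73998453 to 74068431, minus strand), rose from 23.6 ± 0.741 CPM in WT to 68.6 ± 4.30 CPM in Ash1l het (SD, n = 3 each). Its log2 fold change was 1.54 (SE 0.10, adjusted p = 0.00145). Bend6, a BEN domain protein known as a corepressor in Notch signalling (ENSMUSG00000042182; chromosome 1, 33852052 to 33907816, minus strand), rose from 32.3 ± 1.89 to 84.8 ± 9.05 CPM, with a log2 fold change of 1.39 (SE 0.12, adjusted p = 0.00437). For both genes every Ash1l het library lay above every WT library. Usp46 passed with each library left out in turn; Bend6 did not pass without WT replicate 3, where its log2 fold change was 1.41 and its edgeR adjusted p 0.0823. With a globin covariate, chosen after the data were seen, neither passed, at log2 fold changes of 1.45 (SE 0.25) for Usp46 and 1.55 (SE 0.28) for Bend6. Globin levels were higher in every Ash1l het library than in every WT library, so this covariate overlaps with genotype. Changes under it cannot set blood apart from genotype. The quasi-likelihood test called 0 genes lower. Its unadjusted p was under 0.05 for 882 genes, where 763 would be expected by chance; that count ran from 485 (without WT replicate 2) to 1691 (without Ash1l het replicate 3) with single libraries left out, and from 377 to 1089 in the other 9 splits of the samples. DESeq2 called 35 genes, 13 of them lower, and the exact test of edgeR called 39, 13 of them lower.

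**Figure D1:**
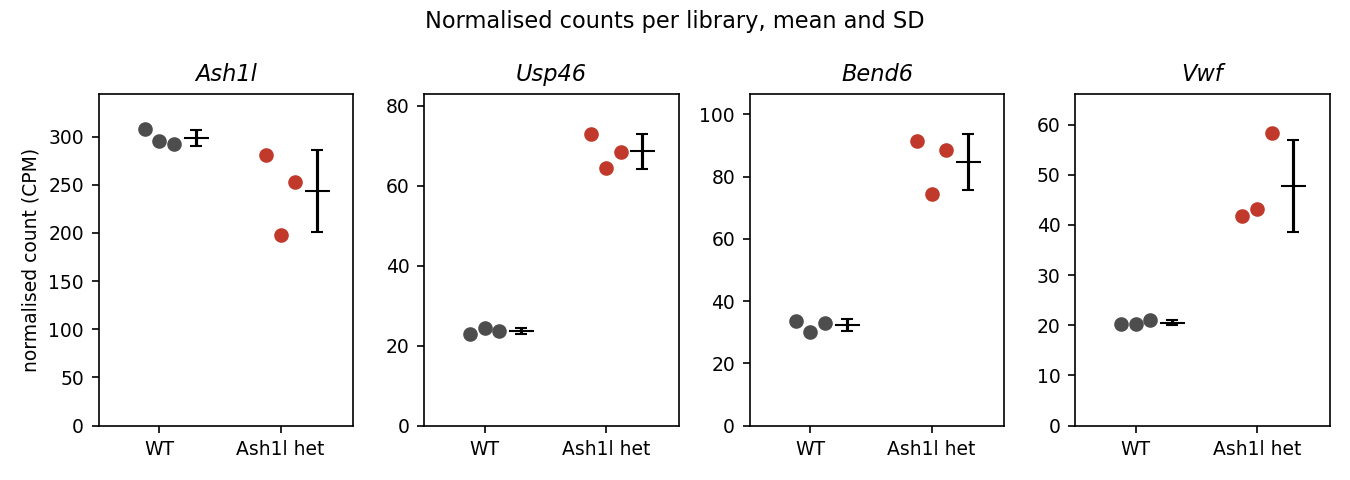
Normalised counts (CPM, y axis) of Ash1l, Usp46, Bend6 and Vwf in each library by genotype (x axis), with points for libraries and the black mark and bars for the mean and SD of 3 libraries. Usp46 lies at 22.9 to 24.3 CPM in WT and at 64.4 to 73.0 CPM in Ash1l het, while the Ash1l groups lie closer together.

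The next 8 genes by unadjusted p did not pass the quasi-likelihood test of edgeR, while DESeq2 and the exact test of edgeR called all 8. Vwf also passed with no low-count filter (adjusted p = 0.00303) and Tnfsf8 by limma-voom (adjusted p = 0.0438). Vwf, the clotting factor carrier made by endothelial cells (chromosome 6, 125546774 to 125686679), was at 20.6 ± 0.506 CPM in WT and 47.7 ± 9.15 CPM in Ash1l het, a log2 fold change of 1.22 (SE 0.15, edgeR adjusted p = 0.0715). It passed without Ash1l het replicate 1 (adjusted p = 0.0310) and without Ash1l het replicate 3 (adjusted p = 0.0403). With the globin covariate its log2 fold change was 1.81 (SE 0.27, edgeR adjusted p = 0.579). The other 7 had an adjusted p of 0.299 by the quasi-likelihood test of edgeR; Spp1 passed without Ash1l het replicate 3 (adjusted p = 0.0407), but its log2 fold change was 0.47 (SE 0.55) with the globin covariate, and Spryd3 passed without Ash1l het replicate 1 (adjusted p = 0.0107). Of these, Ptgs2, which encodes cyclooxygenase-2, had a log2 fold change of 1.57 (SE 0.25), Tmem252 1.98 (SE 0.32), Spp1, which encodes osteopontin, 1.85 (SE 0.30), and Spryd3 1.02 (SE 0.17). The values for Klf10, a zinc finger transcription factor induced by TGF-beta, and Sarm1, an NAD-cleaving enzyme of axon degeneration, were -0.95 (SE 0.16) and -0.81 (SE 0.14). Tnfsf8, the CD30 ligand, had 0 counts in the 3 WT libraries and 65 in the 3 Ash1l het libraries. Its Ash1l het mean of 1.33 ± 0.611 CPM was 20.5-fold above a floor of 3 counts over the WT group. That ratio leaves out the spread of the Ash1l het libraries, at 0.680, 1.89 and 1.43 CPM.

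Of the 38 gene lists tested, 10 passed camera with the preset correlation. With an estimated correlation 0 passed (smallest camera adjusted p = 0.767), and by the directional test of fry 0 passed (smallest adjusted p = 0.674). No list member passed over all genes by the quasi-likelihood test of edgeR on the 6 libraries with genotype as the single term and the default filter. DESeq2 and the exact test of edgeR each called 8 list members over all genes: Vwf, Spp1, Zbtb16 and the 5 blood cell genes. The 10 calls therefore rest on the preset correlation, and both p-values are given for each list.

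Blood and vessel genes were higher in Ash1l het by the preset test. All 5 tested blood cell genes were higher (camera adjusted p = 7.05e-07; adjusted p = 0.767 with an estimated correlation), with a median log2 fold change of 2.04. By the quasi-likelihood test of edgeR all 5 passed when adjusted over the list alone and 0 passed over all genes. Over all genes all 5 passed by DESeq2 (adjusted p from 0.000371 to 0.00365) and by the exact test of edgeR (adjusted p from 0.00196 to 0.0208). The haemoglobin genes Hba-a2, Hba-a1 and Hbb-bt had log2 fold changes of 2.28 (SE 0.49), 2.04 (SE 0.46) and 1.87 (SE 0.44), and Alas2, the first enzyme of erythroid haem synthesis, 2.32 (SE 0.59). With the globin covariate, which is built from 4 of these 5 genes, the list mean was -0.018. The 4 globin genes together stood at 113, 96.8 and 53.6 CPM in the Ash1l het libraries and at 22.9, 33.8 and 21.7 CPM in WT. Of 17 endothelial and mural cell genes, 14 were higher by sign (adjusted p = 0.000848; adjusted p = 0.767 with an estimated correlation), and 1, Vwf, passed when adjusted over the list alone. The transporter Abcb1a, the adhesion molecule Pecam1 and Ly6c1 had log2 fold changes of 0.35 (SE 0.12), 0.35 (SE 0.13) and 0.55 (SE 0.23). The endothelial and mural call was lost without Ash1l het replicate 3 (adjusted p = 0.150).

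Reactive microglia and antigen presentation genes were also higher by the preset test. Of 14 reactive microglia genes, 13 were higher by sign (adjusted p = 3.07e-05; adjusted p = 0.767 with an estimated correlation), and 1, Spp1, passed when adjusted over the list alone. Gpnmb and Clec7a had log2 fold changes of 1.28 (SE 0.44) and 2.50 (SE 0.93), and Lyz2, which encodes lysozyme, stood at 8.78 ± 1.99 CPM in WT and 26.6 ± 18.6 CPM in Ash1l het. Clec7a stood at 8.70, 13.4 and 1.21 CPM in the 3 Ash1l het libraries and at 2.48, 0.957 and 0.811 CPM in WT, so Ash1l het replicate 3 lay within the WT range. All 9 antigen presentation genes were higher by sign (adjusted p = 0.0125; adjusted p = 0.767 with an estimated correlation), and 0 passed when adjusted over the list alone. Cd74, B2m, Tap1 and H2-D1 had log2 fold changes of 0.84 (SE 0.36), 0.70 (SE 0.29), 0.70 (SE 0.44) and 0.74 (SE 0.46). Without Ash1l het replicate 2 the reactive microglia call was lost (adjusted p = 0.0807) and the antigen presentation mean changed sign, to -0.06. With the globin covariate both means changed sign, to -0.47 for reactive microglia and -0.27 for antigen presentation. The antigen presentation call was also lost without WT replicate 2 (adjusted p = 0.0709) and on log2(FPKM + 0.1) (adjusted p = 0.0670).

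**Figure D2:**
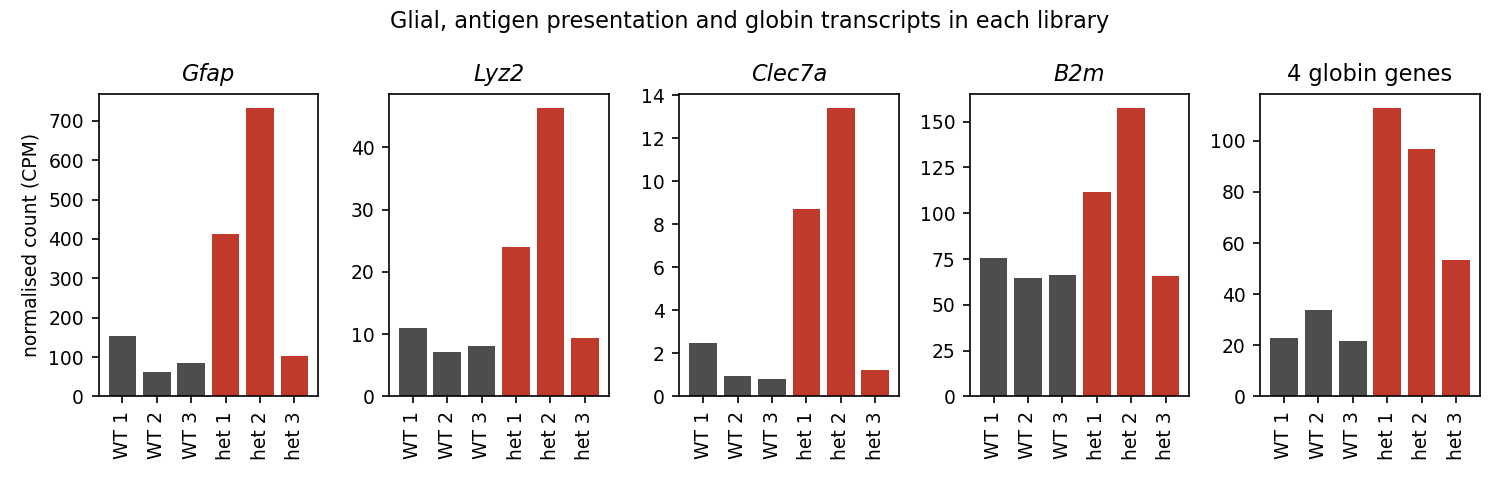
Normalised counts (CPM, y axis) of Gfap, Lyz2, Clec7a, B2m and the 4 globin genes together in each of the 6 libraries (x axis), as bars from 0. For the 4 single genes Ash1l het replicates 1 and 2 lie above all WT libraries and Ash1l het replicate 3 lies within the WT range, while the globin sum is higher in all 3 Ash1l het libraries. These genes were chosen with their values in view, to show a spread within a group. Others differ: in Ash1l het replicate 3 Spp1, Serpina3n, Vim, Lcn2 and Lrg1 lay above all WT libraries, H2-D1 within their range and H2-K1 below it.

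Spiny projection neuron and synaptic lists were lower by small amounts with the preset correlation and genotype as the single term. Of 22 genes shared by spiny projection neurons, the principal neurons of the striatum, 17 were lower by sign (adjusted p = 0.000624; adjusted p = 0.767 with an estimated correlation), with a median log2 fold change of -0.17. Syndig1l, Bcl11b, Pde1b and Adcy5 had values of -0.40 (SE 0.15), -0.33 (SE 0.14), -0.28 (SE 0.13) and -0.22 (SE 0.13). Of 22 synaptic adhesion and scaffold genes, 20 were lower by sign (adjusted p = 0.000624; adjusted p = 0.767 with an estimated correlation), among them Shank3 at -0.45 (SE 0.19), Nlgn3 at -0.29 (SE 0.13), Dlgap4 at -0.29 (SE 0.14) and Nrxn2 at -0.32 (SE 0.16). Of 17 synaptic vesicle release genes, 14 were lower by sign (adjusted p = 0.00351; adjusted p = 0.767 with an estimated correlation), with Stx1a at -0.36 (SE 0.13), Cplx2 at -0.34 (SE 0.13), Cplx1 at -0.30 (SE 0.16) and Rab3a at -0.23 (SE 0.14). In these 3 lists 0 genes passed when adjusted over the list alone. With the globin covariate the 3 means changed sign, to 0.15, 0.12 and 0.065. Ash1l het replicates 1 and 2, which had the highest Gfap, Clec7a and globin levels, lay at -28.1 and -28.5 on the first principal component, and the other 4 libraries between 4.18 and 23.8. Without Ash1l het replicate 2 the adhesion and scaffold call (adjusted p = 0.130) and the vesicle release call (adjusted p = 0.795) were lost.

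Of 25 autism-associated genes, 16 were lower by sign (adjusted p = 0.0240; adjusted p = 0.961 with an estimated correlation), and 0 passed when adjusted over the list alone. The leading members were Adnp, at -0.48 (SE 0.15), Shank3 and Nlgn3, which the adhesion list also holds, and Tcf4, at -0.23 (SE 0.12). Counts of Adnp overlap those of the model Gm20716 on the same strand, which was higher in Ash1l het, and the sum of both had a log2 fold change of 0.07. The list mean changed sign without Ash1l het replicate 2, to 0.025, and with the globin covariate, to 0.015, and the call was lost without WT replicate 1 (adjusted p = 0.184) and on both FPKM scales (adjusted p = 0.0714 and 0.0585).

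Glucocorticoid response genes were higher by sign for 10 of 11 (adjusted p = 0.00518; adjusted p = 0.767 with an estimated correlation), and 0 passed when adjusted over the list alone. Zbtb16, a zinc finger transcription factor, had a log2 fold change of 1.35 (SE 0.34), and Sult1a1, Fkbp5 and Cdkn1a had 0.53 (SE 0.31), 0.21 (SE 0.12) and 0.32 (SE 0.20). That call was lost without Ash1l het replicate 2 (adjusted p = 0.0807) and without WT replicate 2 (adjusted p = 0.368). Of 48 cytosolic ribosomal protein genes, 43 were higher by sign (adjusted p = 0.0106; adjusted p = 0.961 with an estimated correlation), with Rps25 at 0.39 (SE 0.17) and Rpl26 at 0.34 (SE 0.18), and 0 passed when adjusted over the list alone. Ribosomal protein genes summed to 3070 CPM in Ash1l het replicate 2 and to between 1973 and 2398 CPM in the other 5 libraries. The ribosomal mean changed sign without Ash1l het replicate 2, to -0.10, and the call was lost without WT replicate 1 (adjusted p = 0.140) and with the globin covariate (adjusted p = 0.257).

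**Figure D3:**
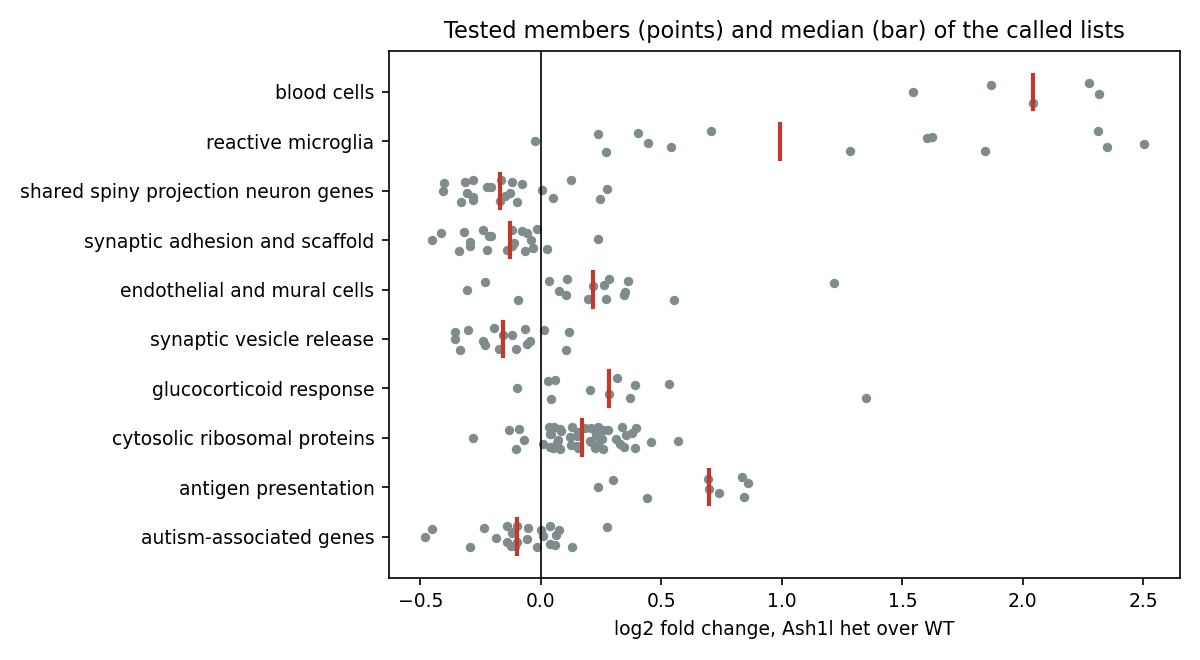
Log2 fold changes of Ash1l het over WT (x axis) for the tested members of the 10 lists that passed camera with the preset correlation (y axis), with points for genes and a red bar for the median. The blood cell median is 2.04 and the shared spiny projection neuron median is -0.17.

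The other 28 lists did not pass with all 6 libraries and genotype as the single term. Indirect-pathway spiny projection neuron genes came nearest (7 of 8 lower by sign, camera adjusted p = 0.0543; adjusted p = 0.767 with an estimated correlation and 0.674 by fry). With the preset correlation that list passed with no low-count filter (adjusted p = 0.0399), with a replicate block (0.0252), with a surrogate variable (0.0285), without Ash1l het replicate 3 (0.0105) and without WT replicate 1 (0.0462). Its leading members were the adenosine receptor gene Adora2a, at -0.42 (SE 0.18), and Sp9, at -0.37 (SE 0.17). Direct-pathway genes had a camera adjusted p of 0.885, and their precursor of substance P, Tac1, was the single member to pass when adjusted over the list alone, at 155 ± 7.30 CPM in WT and 208 ± 16.2 CPM in Ash1l het (log2 fold change 0.42, SE 0.10). The fry p for changes in either direction was 0.00099 for the direct-pathway list. It was the smallest of the 38 lists and was not adjusted over them. Circadian clock, dopamine signalling and glutamate receptor lists had camera adjusted p-values of 0.126, 0.166 and 0.176. Histone H3K36 methylation and Polycomb machinery had 10 genes higher and 10 lower by sign (adjusted p = 0.959), HOX, MEIS and PBX homeobox genes 3 and 3 (adjusted p = 0.908), and neighbours of Ash1l on chromosome 3 had 11 higher and 18 lower (adjusted p = 0.765). Marker lists of astrocytes (0.806), oligodendrocytes (0.491), oligodendrocyte precursors (0.491), homeostatic microglia (0.798), ependymal cells (0.798), choroid plexus (0.277) and meningeal fibroblasts (0.883) did not pass by camera adjusted p. Neither did lists of striosome neurons (0.733), cholinergic interneurons (0.798), GABA interneurons (0.733), cortical glutamatergic neurons (0.561), thalamic neurons (0.735) and ventral and medial striatum (0.491). Camera adjusted p-values were 0.537 for immediate-early genes, 0.951 for GABA receptors and synthesis, 0.885 for oxidative phosphorylation and 0.906 for mitochondrially encoded genes. They were 0.798 each for the interferon response, the unfolded protein and heat shock response and cholesterol synthesis. Some of these results changed with a left-out library or a covariate. Without Ash1l het replicate 3 the circadian clock (adjusted p = 0.0393), dopamine signalling (0.0358) and glutamate receptor (0.0277) lists passed as lower, and the oligodendrocyte (7.64e-05) and interferon response (0.00643) lists as higher. The circadian clock list also passed as lower with all 6 libraries and a surrogate variable (0.0446), and the oligodendrocyte list passed in the opposite direction, as lower, with the globin covariate (0.000556). GABA interneuron genes (0.00901) and neighbours of Ash1l (0.0439) passed as higher with that covariate. Without Ash1l het replicate 1 the cortical list passed as lower (0.00487). Immediate-early genes passed as higher without WT replicate 3 (0.000883). Oxidative phosphorylation passed as higher without Ash1l het replicate 1 (0.00573) and as lower without Ash1l het replicate 2 (4.78e-05). For the astrocyte, cortical, cholinergic, oxidative phosphorylation, mitochondrial, homeobox and H3K36 lists the median, the mean and the test did not all have the same sign. Gfap, the astrocyte intermediate filament, stood at 412, 733 and 104 CPM in the Ash1l het libraries and at 154, 62.1 and 83.7 CPM in WT (log2 fold change 2.06, SE 0.81).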

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

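The 2 calls, Usp46 and Bend6, were also made by every alternative that used all 6 libraries except the globin covariate, which was chosen after seeing the data. DESeq2 called 35 genes (22 higher, 13 lower) and the exact test of edgeR 39 (26 higher, 13 lower), with 29 shared. In simulated data both called more unchanged genes than the quasi-likelihood test. Leaving out single libraries gave 1 to 13 calls, 1 to 9 of them higher and 0 to 5 lower. With the globin covariate 0 genes passed (0 higher), and 346 had an unadjusted p under 0.05. There the Usp46 log2 fold change was 1.45 (SE 0.25, against 0.10 without it). Globin was higher in every Ash1l het library than in every WT library, and a covariate that overlaps with genotype widens the SE. Calls lost and signs changed under it therefore do not show that blood accounts for a result. With the same covariate Spp1 moved from 1.85 to 0.47, while Vwf moved from 1.22 to 1.81 and Spryd3 from 1.02 to 1.44. The Ash1l log2 fold change ran from -0.41 to -0.16 and passed nowhere. The fit with a replicate block called 3 genes, adding Hba-a1, and 11 lists. Same-numbered libraries deviated from their group means with correlations of 0.0556, -0.0753 and 0.0107. Differently numbered libraries of opposite genotype ran from -0.13 to 0.126, so no pairing by number was seen. A pairing with a small effect could give such values too, so whether the numbers pair the samples stays unknown. The number of called lists, 10, became 0 with an estimated correlation, 0 by fry, 5 with the globin covariate and 4 to 15 with single libraries left out. Of the 5, 2 were among the 10 (endothelial and mural cells, glucocorticoid response) and 3 were not (GABA interneurons, oligodendrocytes, neighbours of Ash1l). Under that covariate the endothelial and mural mean rose from 0.22 to 0.41 and the glucocorticoid mean from 0.32 to 0.56. The ribosomal protein mean went from 0.17 to 0.13. With the globin covariate the list means reversed to -0.018 (blood cells), -0.47 (reactive microglia), 0.15 (shared spiny projection neuron genes), 0.12 (adhesion and scaffold), 0.065 (vesicle release), -0.27 (antigen presentation) and 0.015 (autism-associated genes). Without Ash1l het replicate 2 the means of 3 lists reversed; with single libraries left out they ran from -0.098 to 0.34 (ribosomal proteins), from -0.058 to 0.91 (antigen presentation) and from -0.17 to 0.025 (autism-associated genes). The cause of these changes was not tested. DESeq2, the exact test, limma-voom and the other thresholds gave no separate list value. In simulated data 8% of genes changed 1.5-fold were recovered, so small changes were mostly not detectable at this depth and sample number.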

Other observations

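Some genes that DESeq2 and the exact test of edgeR both called were not called by the quasi-likelihood test and belong to no list above; they are named here after their values were seen. Lrg1, Lcn2, Osmr and Cp, genes known to respond to inflammation, had log2 fold changes of 3.85 (SE 0.66), 2.66 (SE 0.52), 1.32 (SE 0.24) and 0.67 (SE 0.12). Their adjusted p-values by the quasi-likelihood test were 0.299, 0.620, 0.422 and 0.396. The intermediate filament gene Vim had 1.05 (SE 0.23), and Gdf10, Otof and Ryr1 had -0.94 (SE 0.16), -0.87 (SE 0.19) and -0.63 (SE 0.13). The 2 annotated models of Myh14 moved apart, at -1.51 and 0.93, while their sum had a log2 fold change of -0.07, so that pair is uncertain.

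The tests below of neighbouring reads, blood, vessel content and sex were chosen after the results they concern had been seen. The test of other splits was written before. The strain segment test is centred on Usp46 and Bend6, so it also followed those calls. The list of vessel inflammation genes was not among the gene lists fixed before the data were examined, and it concerns results already seen. Of the 10 splits of the 6 samples, 3, the real one included, called as many genes as the real split, which called 2; the highest other split called 3. For lists, 5 splits gave as many, the real one included, with 10 in the real split and 18 in the highest other. With 10 splits no share under 0.05 can be reached. The other splits called 5 to 18 lists with the preset correlation, several of them more than the real one. Whether this reflects the preset correlation or a structure of the samples was not tested. On the first principal component (27.9% of variance) Ash1l het replicates 1 and 2 lay at -28.1 and -28.5, and the other 4 libraries between 4.18 and 23.8. On the second (26.0%) the same pair lay at opposite ends, at 34.8 and -34.3, so they stand apart from the rest and from each other.

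Usp46 and Bend6 lie on different chromosomes from Ash1l and from each other. The 12 tested genes within 400 kb of either had a median log2 fold change of 0.057 (95% limits -0.07 to 0.30 from a bootstrap over genes). Genes overlapping on the same strand held at most 1.31% of the counts of either, which argues against reads shared with those genes. Overlaps on the opposite strand, or with gene models whose strand is unknown, were not checked. A median could also miss a single neighbour that shares reads. A strain segment carried over around each gene stays open: 3 of 101 tested genes within 5 Mb had an unadjusted p under 0.05 (one-sided Fisher exact test, p = 0.936), and such a segment need not change its other genes. An effect of Ash1l heterozygosity is a candidate explanation that these data cannot set apart from such a segment.

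Vwf was higher in Ash1l het by DESeq2 (adjusted p = 3.86e-08), the exact test of edgeR (1.37e-07) and the quasi-likelihood test with no filter (0.00303) but did not pass that test with the default filter (0.0715), and the reactive microglia and blood lists passed as higher by the preset test only (adjusted p = 0.767 for each with an estimated correlation); the microglia call was lost without Ash1l het replicate 2 (adjusted p = 0.0807). More vessel in the tissue is argued against for Vwf alone, although larger vessels were not tested. The 9 core endothelial markers had a median log2 fold change of 0.22 (bootstrap 95% limits 0.03 to 0.35), below the lower 95% limit of Vwf, 0.89. That bootstrap drew genes, so its limits measure the spread between genes and not between libraries. The mean of the endothelial and mural list, which holds Vwf, ran from 0.10 to 0.30 with single libraries left out. Blood left in the tissue cannot be told apart from the rest. With the globin covariate, which overlaps with genotype, the Vwf log2 fold change was 1.81 (SE 0.27), against 1.22 without it. The reactive microglia mean was -0.47 there, against 1.15. A criterion summed the CPM of the endothelial and mural and the reactive microglia lists (31 genes). Abundant genes weigh most in such a sum, so it cannot decide for Vwf. Over the 9 pairings of an Ash1l het with a WT library the sum gained -2.88 to 22.2 times the globin gain. That was the criterion first written; 2 narrower ones were set later, with the values in view, and give no verdict here (Vwf alone, 22.6% to 192% of the globin gain; 6 microglia genes, 0.0442 to 1.48 times). Systemic inflammation may contribute and stays open. Of 25 other vessel response genes given, 17 were tested and 14 were higher by sign. Camera gave p = 9.89e-06 at the preset correlation and p = 0.0589 with an estimated correlation. The unadjusted quasi-likelihood p was under 0.05 for 6 of the 17. The most abundant members, Vcam1 and Ackr1, had log2 fold changes of -0.04 (SE 0.14) and 0.01 (SE 0.28).

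All 6 libraries carry transcripts of female tissue although the protocol in the labels says male. Y-linked rows lost in counting of male tissue alone would leave Xist near 0, and its lowest level was 1956 CPM. A mixture of male and female tissue is argued against by the Y-linked share of reads of 4 X and Y gene pairs, whose highest upper 95% limit (exact binomial) was 0.0947%. That holds only if Y-linked reads were counted. A mixture whose Y-linked reads were lost in counting would give the same values. The pattern holds in both genotypes, so it does not separate them; an error in the description of sex is a candidate explanation that was not tested against any record.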
